A study of Mus musculus with 2 samples.

How the data were processed

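RNA of mouse ureters at postnatal day 4 was measured on 2 two-colour Agilent arrays of one custom design, each with 174979 spots, of which 157716 were not control spots. These spots held 39429 probes of 60 bases, with 4 spots per probe. Per the labels, total RNA was isolated with peqGOLD RNAPure and turned into labelled cRNA with an amino allyl amplification kit. Each array held an RNA from Tbx18(cre/+);Rbpj(fx/fx) ureters, called Rbpj-cKO, in one channel and a control RNA in the other. The control genotype was Tbx18(+/+), with one floxed Rbpj allele and a second that was not determined, so the groups also differed in the Tbx18 allele that carries cre. Array 1 held a female pair, with the Rbpj-cKO RNA in the red channel (Alexa647), and array 2 a male pair with the dyes exchanged. Neither the number of animals behind an RNA nor whether RNAs were pooled is given in the sources used here, so no p-value measures the spread between animals. Those of limma rest on the spread between these 2 pairs, combined with a prior across genes. Those of camera at its preset correlation and of the permutation tests rest largely on the scatter among genes. Sex, dye orientation and replicate changed together, and none could be fitted beside the genotype. A dye effect cancels in the mean of the 2 arrays. Per the file headers, both arrays lay on 1 slide and were scanned on 1 day, so neither served as a batch.

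Per the file headers and the submitters' processing notes, the deposited spot values are fluorescence intensities extracted with Agilent Feature Extraction 10.7.3.1. The deposited log ratio is a log10 value of red over green processed signal, per the file headers, and was within 0.02 of that quotient at 93.5% of gene spots. The values of the authors' deposited series table are a score whose making is not given in the sources used here. They were read as signed fold changes, because none lay between -1 and 1 and their size and sign followed the log ratios of Rbpj-cKO over control. The median of each column was 1, 31.8% of the values on array 1 and 31.6% on array 2 were exactly 1, and after conversion to log2 the correlation with the scanner log ratio across probes was 0.777 and 0.686. How the authors centred or floored these deposited values is not given in the sources used here, and the table served only as an alternative.

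Mean signals were corrected with normexp on the local background medians (offset 50) and normalized by loess within each array, with control spots at weight 0. Spots with an outlier flag were dropped (3.34% on array 1 and 3.12% on array 2), and no spot was saturated. Ratios were turned to Rbpj-cKO over control on both arrays, and the spots of a probe were averaged. A probe was kept if more than 50% of its spots were well above background on both arrays in the channel of at least 1 genotype, which 28182 probes were. Each gene was represented by its brightest probe. Gene names came from a match of the probe's accession to RefSeq names of assembly GRCm38.p6, which succeeded for 28328 probes and changed 1359 names. The other 11101 probes kept the name in the file. Probe coordinates are those of the files (mm9). This left 21150 genes, of which 15763 had a gene name and 5387 a clone, model or accession name.

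The log2 ratios were tested against 0 with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. Each gene had 1 residual degree of freedom, and the prior across genes raised this to 4.35. Because 2 arrays give few degrees of freedom, genes changed at least 1.5-fold in the same direction on both arrays were also counted, beside those changed as much in opposite directions. The 27 gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. The estimated correlation and fry rest on the 1 residual degree of freedom, so they could hardly call any list. SDs are between the 2 arrays (n = 2). The design, the gene lists and the rule for naming genes were fixed before the data were examined. The rule takes Rbpj and Tbx18, the 15 highest and 15 lowest gene names, first from genes past the adjusted threshold and at least 1.5-fold changed on both arrays and then from those that only met the size rule, and per list the members past the threshold or up to 4 with the largest mean log2 ratio. Of the Notch and smooth muscle lists any measured member may be named. Genes named outside the rule are marked as chosen after their values were seen.

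The pipeline was tested on simulated arrays with 200 changed genes among 21150. It called 11.9% of the genes changed 1.5-fold, 82.1% of those changed 2-fold and 100% of those changed 4-fold. It also called 22 unchanged genes. Even with all 200 changed genes called, these 22 would be a larger share of the calls than the adjusted threshold aims for. The size rule took 8 unchanged genes as higher and 13 as lower, and 24 differed as much in opposite directions. A list shifted by 0.5 on the log2 scale was called, and 0 of 26 unshifted lists were. The simulated genes varied independently, so this says nothing about lists whose genes move together. The percentages called hold only for the changes as simulated. On the real arrays 15 genes were at least 2-fold higher on both and 48 at least 2-fold lower, but limma called only 1. Cfd, with log2 ratios of -4.73 on array 1 and -2.22 on array 2, was not called (adjusted p = 0.179 in limma).

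Alternatives were the scanner's own log ratio, an offset of 16, no background subtraction, median centring, scaling between arrays, no filter on dim probes or one on both channels of both arrays, the mean of a gene's probes or each probe alone, eBayes with trend and robust settings, the 4 channels in a 2-group fit, the deposited series table, a regression on the GC share of the probe, an adjusted p under 0.1, a 2-fold size rule, and leaving out each replicate. Leaving out saturated spots changed nothing, since there were none.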

Results

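The data compare ureters of mouse pups that lack Rbpj in the Tbx18 lineage with control ureters at postnatal day 4. Rbpj encodes the DNA-binding protein through which Notch receptors act on transcription, and Tbx18 is expressed in the undifferentiated mesenchyme that surrounds the ureteric epithelium and forms the smooth muscle coat and fibroblast layers. The series asks which transcripts differ between such ureters. Two-colour arrays gave 2 pairs, a female pair on array 1 and a male pair on array 2 with the dyes exchanged, so each value rests on n = 2 arrays, whose number limits the precision. Of the gene spots, 72.2% (red) and 73.1% (green) were well above background on array 1, and 71.8% and 74.0% on array 2. The median SD between the 4 spots of a probe was 0.05 on the log2 scale on array 1 and 0.06 on array 2. Values are log2 ratios of Rbpj-cKO over control, negative where the Rbpj-cKO RNA was lower.

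The targeted gene Rbpj was about 2-fold lower in the Rbpj-cKO RNA of each pair. Its log2 ratio was -0.92 on array 1 and -1.10 on array 2, with a mean of -1.01 ± 0.13 (SD, n = 2) and an adjusted p of 0.0875 in limma. The probe lies on chromosome 5 at 54048503-54048562 (mm9), and a dimmer probe at 54044777-54044836 gave -0.84. Whether either probe lies in the deleted part was not determined, so they do not settle whether the labels hold. Tbx18, of which 1 allele carries cre in the Rbpj-cKO mice, stood at 0.08 ± 0.11 (adjusted p = 0.742). The sex-linked genes matched the labels on array 2, where both RNAs had Y-linked transcripts and Xist was not well above background. On array 1, labelled female in both channels, Xist was well above background in both RNAs, but the Y-linked genes Ddx3y and Eif2s3y were higher in the Rbpj-cKO RNA by 4.23 and 4.26 on the log2 scale. Directions below therefore rest on an Rbpj-cKO RNA of array 1 whose sex label the Y-linked genes do not match.

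Across the 21150 genes tested, the ratios of the 2 arrays correlated with Pearson's r = 0.454 and Spearman's rho = 0.391, where genes are not independent replicates, and Pearson's r was 0.169 with median centring. Only Ucp1, the uncoupling protein of brown fat, passed the adjusted threshold of limma. It fell by 2.74 on the log2 scale on both arrays, to 0.149 of the control level (adjusted p = 0.0249, lower on 2 of 2 arrays). Its 2 ratios nearly coincided (SD 0.0018). Other fat markers fell about as far or further but unequally on the 2 arrays, and did not pass, such as Cidea (-2.70 ± 0.96) and Cfd (-3.47 ± 1.77). No gene was called higher (0 genes, smallest adjusted p 0.084). At an unadjusted p under 0.05, limma gave 1478 higher and 1485 lower genes, where 1058 in all are expected if nothing changed, and eBayes with trend and robust settings called 46 higher and 49 lower genes. By size alone, 85 genes were at least 1.5-fold higher and 168 at least 1.5-fold lower on both arrays, against 22 that differed as much in opposite directions. These counts were 247 and 265 with the scanner's log ratio, and 154 and 209 with the deposited series table. The call of Ucp1 was lost with the scanner's log ratio, median centring, scaling between arrays, the 4 channels in a 2-group fit and the deposited series table.

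**Figure D1:**
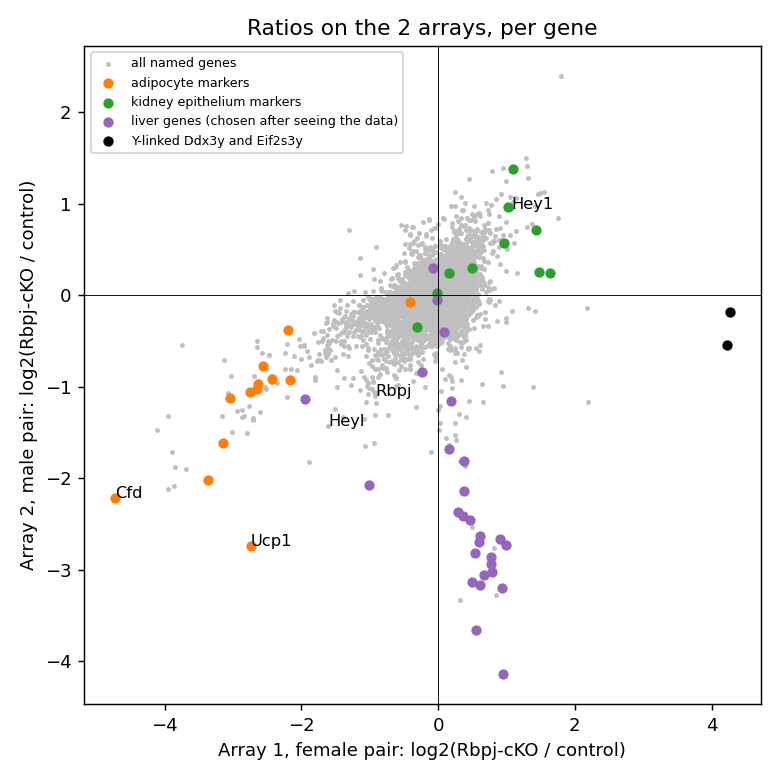
Log2 ratio of Rbpj-cKO over control on array 1 (female pair, horizontal axis) and array 2 (male pair, vertical axis). Each point is a named gene. Adipocyte markers lie at the lower left, with list medians of -2.64 and -1.02, 8 of 10 kidney epithelium markers at the upper right, and the liver genes, chosen after the data were seen, are low on array 2 with a median of -2.63. Ddx3y and Eif2s3y lie far right.

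Markers of fat cells were among the genes with the lowest ratios. The adipocyte list fell as a group (13 of 13 members lower on both arrays, camera adjusted p = 8.44e-12), with a median of -2.64 on array 1 and -1.02 on array 2. With an estimated correlation its adjusted p was 0.653. Past the threshold over all genes was 1 member, Ucp1, and 12 were past it adjusted over the list alone. The 15 lowest named genes were Ucp1, Cfd, Ces1d, Cox8b, Otop1, Slc36a2, Mrap, Pck1, Cidea, Acvr1c, Cidec, Ces1f, Magel2, Adig and B3galt2, with mean log2 ratios between -3.47 and -2.11. Of these, Cfd, the serine protease adipsin secreted by fat cells, had -3.47 ± 1.77 (adjusted p = 0.179), and Cidea, a lipid droplet protein of brown fat, -2.70 ± 0.96 (adjusted p = 0.133). The ratios of Cfd were -4.73 on array 1 and -2.22 on array 2. The 2 probes of Otop1 differed, with -2.86 and -1.29.

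The 15 highest named genes were Mybpc1, Cntn6, Crym, Cntn4, Tac1, Slpi, Esr1, Nap1l2, Kap, Six2, Col6a5, Brinp3, Serpina6, Cltrn and Ptprv, with mean log2 ratios between 1.07 and 2.10 and adjusted p between 0.084 and 0.181. Mybpc1, a myosin-binding protein of slow skeletal muscle, had 2.10 ± 0.42. Cntn6 and Cntn4, adhesion molecules of the contactin family, had 1.39 ± 0.15 and 1.34 ± 0.30. Esr1, the oestrogen receptor alpha, had 1.30 ± 0.02, although the probes of this gene ranged from 0.61 to 1.30. Tac1, which encodes substance P, had 1.30 ± 0.27. Six2, a transcription factor of nephron progenitors, had 1.19 ± 0.31, with its second probe at 0.37.

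Among Notch target genes the ratios went both ways. Of the 10 measured Notch target genes, Heyl had -1.61 on array 1 and -1.44 on array 2 (mean -1.52 ± 0.12, adjusted p = 0.084) and Hey2 had -0.39 ± 0.03. In the other direction, Hey1 had 1.00 ± 0.09 (adjusted p = 0.084) and Hes5 had 0.40 ± 0.06. Hes5 and Hey2 were dim, with mean log2 intensities of 7.67 and 7.95, against 12.3 for Hey1 and 11.1 for Heyl. Hes1 had 0.18 ± 0.02. None of the 10 passed over all genes (0 genes), and 4 did adjusted over the list alone (Heyl, Hey1, Hey2 and Hes5). As a group the targets were not called (camera adjusted p = 0.656, with a positive median of 0.02 and a negative mean of -0.03), nor were the 25 Notch pathway components (adjusted p = 0.382). Of the components, 9 were higher and 9 lower on both arrays, and Rbpj, Dlk1 and Notch3 passed adjusted over the list alone. Dlk1, a non-canonical ligand also made by fat cell precursors, had -0.71 ± 0.18, and Notch3, the receptor of vascular smooth muscle and pericytes, -0.41 ± 0.03.

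Smooth muscle genes fell as a group. Of the 25 contractile proteins, 18 were lower on both arrays and 0 higher on both (camera adjusted p = 1.55e-07, 0.653 with an estimated correlation), with list medians of -0.10 on array 1 and -0.32 on array 2. The lowest ratios were those of the intermediate filament proteins synemin and desmin, with -1.13 ± 0.21 for Synm and -0.74 ± 0.12 for Des, followed by Cald1 with -0.44 ± 0.12. Past the threshold over all genes were 0 members, and 5 passed adjusted over the list alone (Synm, Des, Cald1, Synpo2 and Ppp1r14a). Members differed in how far the pairs were alike. Acta2, smooth muscle actin, had 0.20 on array 1 and -0.36 on array 2, and Tagln, transgelin, 0.20 and -0.34, whereas Smtn, smoothelin, had -0.28 and -0.32. Because the dyes were exchanged, a dye bias of the Acta2 and Tagln probes would also give opposite signs, which was not tested. Cnn1, calponin, was lower on both arrays but by unlike amounts, -0.07 and -0.39. Myh11, smooth muscle myosin, had -0.15 ± 0.07. Myocd, the coactivator of the smooth muscle programme, is in the list of ureteric mesenchyme transcription factors and had -0.12 ± 0.21. It lies outside the rule for naming genes and was chosen after its value was seen. The 24 measured ion channels and receptors of contraction also fell as a group (adjusted p = 0.0122, 0.653 with an estimated correlation), with 12 lower and 6 higher on both arrays. In that list P2rx1, an ATP-gated channel of smooth muscle, had -1.06 on array 1 and -0.93 on array 2 (adjusted p = 0.084), and Ednrb, an endothelin receptor, -0.46 ± 0.17. Beside both lists, the adipocyte markers were lower and the kidney markers higher in the same RNAs.

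Vascular lists were called lower too. Pericyte markers fell (6 of 8 lower on both arrays, camera adjusted p = 0.000369, 0.653 with an estimated correlation), among them Kcnj8 with -0.70 ± 0.05, Pdgfrb with -0.64 ± 0.11 and Ndufa4l2 with -0.58 ± 0.12, and 5 members passed adjusted over the list alone. Endothelium markers fell too, with 11 of 17 lower on both arrays (adjusted p = 0.000787, 0.706 with an estimated correlation) and Cldn5 lowest at -0.53 ± 0.36. Erythroid markers fell, with 9 of 9 lower on both arrays (adjusted p = 3.04e-05, 0.653 with an estimated correlation) and a median of -0.25. The globin genes of this list are near-identical copies that were not separated here. In the same RNAs the adipocyte medians were -2.64 and -1.02.

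**Figure D2:**
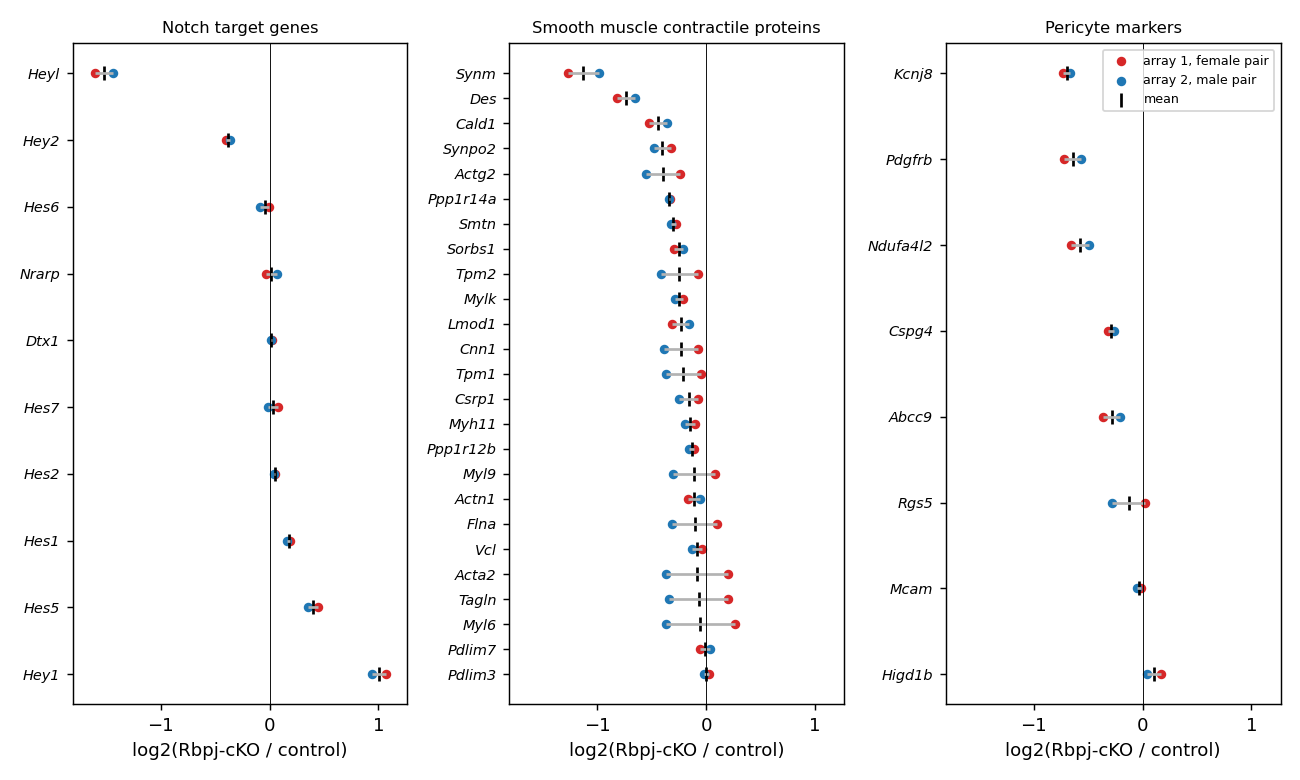
Log2 ratio of Rbpj-cKO over control (horizontal axes) of the measured Notch target genes, smooth muscle contractile proteins and pericyte markers. Red points are array 1, blue points array 2, bars their mean, and grey lines join the arrays. Heyl and Synm are lowest and Hey1 is highest, while Acta2 and Tagln lie on opposite sides of 0 on the 2 arrays.

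Markers of neighbouring tissues also differed. Kidney epithelium markers rose as a group, with 8 of 10 higher on both arrays (adjusted p = 3.04e-05, 0.653 with an estimated correlation) and medians of 1.00 on array 1 and 0.28 on array 2. Kap, the kidney androgen-regulated protein, had 1.24 ± 0.20 and Lrp2, the megalin receptor of the proximal tubule, 0.99 ± 0.05, whereas Aqp1, a water channel named after its value was seen, had -0.33 ± 0.03 (adjusted p = 0.0146 over the list alone). Mesothelium markers rose (5 of 7 higher on both arrays, adjusted p = 0.000167, 0.706 with an estimated correlation), with Gpm6a at 1.02 ± 0.39 and Lrrn4 at 0.89 ± 0.14. The list shares Krt19 and Upk1b with the urothelium list, which rose with 10 of 21 higher on both arrays (adjusted p = 0.00359, 0.775 with an estimated correlation), by medians of 0.28 on array 1 and 0.04 on array 2. Skeletal muscle markers fell (7 of 11 lower on both arrays, adjusted p = 0.000787, 0.653 with an estimated correlation), with Myh8 at -1.38 ± 0.19 and Ckm at -0.80 ± 0.02. Proliferation genes were called lower (adjusted p = 0.00827, 0.790 with an estimated correlation), but their medians were -0.35 on array 1 and 0.07 on array 2, with 5 of 24 lower on both arrays. Immediate early genes were called lower (adjusted p = 0.0282, 0.653 with an estimated correlation), with Egr2 at -0.54 ± 0.18.

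Of the signalling pathways, the BMP list rose (14 of 18 higher on both arrays, adjusted p = 0.00104, 0.653 with an estimated correlation). Bmpr1b, a type I BMP receptor, had 0.61 ± 0.02, Id4, a BMP target, 0.47 ± 0.08, and Bmp2 0.39 ± 0.11. Elastic fibre genes rose (9 of 17 higher on both arrays, adjusted p = 0.0144, 0.706 with an estimated correlation), with Efemp1 at 0.46 ± 0.15 and the cross-linking enzyme Lox at 0.45 ± 0.09. The WNT list was called higher (adjusted p = 0.0282, 0.719 with an estimated correlation), with 10 of 26 higher on both arrays and Lgr5 at 0.64 ± 0.41. The retinoic acid list was called higher (adjusted p = 0.0471, 0.653 with an estimated correlation), with 6 of 15 higher on both arrays, and its highest members were Cyp26b1, an enzyme that degrades retinoic acid, at 1.06 ± 0.06 (adjusted p = 0.084) and Aldh1a3, which makes it, at 0.42 ± 0.32. Crabp1, of the same list, went the other way, with -0.70 ± 0.51. Of 15 alternatives, which include the estimated correlation and fry, 11 ended the call of the retinoic acid list, 7 that of the WNT list, 4 each those of the urothelium and immediate early lists, and 3 that of the elastic fibre list. The estimated correlation and fry ended every call, which says little on 1 residual degree of freedom. In the same RNAs the medians on arrays 1 and 2 were -2.64 and -1.02 for adipocyte markers, 1.00 and 0.28 for kidney epithelium markers and 0.90 and 0.14 for mesothelium markers. Not called were the ureteric mesenchyme transcription factors (adjusted p = 0.0618), fibroblast markers (0.195), interferon response genes (0.203), steroidogenic cell markers (0.281), the TGF-beta pathway (0.382), the hedgehog pathway (0.789), nerve and Schwann cell markers (0.791), injury and inflammation genes (0.869) and leukocyte markers (0.997). The first of these was called higher under 3 of the 15 alternatives (no filter on dim probes, trend and robust settings, and the series table), with 0.0336 as its smallest adjusted p. In these lists Pdgfra, a fibroblast marker, had 0.47 ± 0.03, Foxd1 0.36 ± 0.26, Uchl1 -0.70 ± 0.08 and Vcam1 0.73 ± 0.22.

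In total, camera called 16 of the 27 lists, 7 higher and 9 lower. With an estimated correlation 0 lists were called (smallest adjusted p 0.653), and fry called 0 (smallest adjusted p 0.14).

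**Figure D3:**
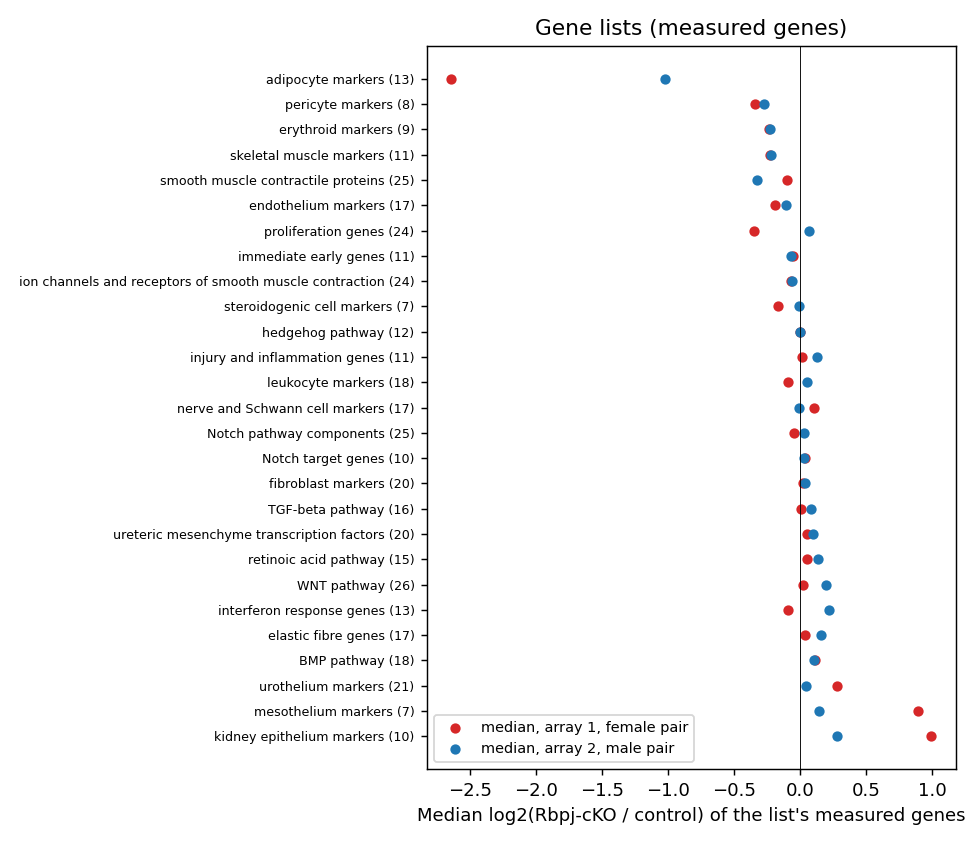
Median log2 ratio of Rbpj-cKO over control of each gene list (horizontal axis) on array 1 (red) and array 2 (blue), with the number of measured genes in brackets. Adipocyte markers are lowest on both arrays, and kidney epithelium and mesothelium markers are highest on array 1.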

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

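The tests in this part were all chosen after the values were seen. Opposite directions in the 2 pairs, one female and one male, drew attention to 22 genes that were at least 1.5-fold higher in one and lower in the other. Of these, 21 were higher in the female and lower in the male pair and 1 the other way, while the simulated arrays gave 24 unchanged genes, 11 and 13. The simulated noise was drawn from the spread fitted to these same 2 arrays, so the 24 are no independent level for the 22. The difference between the pairs was not tested, since each sex has 1 pair. Spp1, a gene of the injury list, had 2.19 in the female pair and -1.17 in the male pair.

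Of the 22, 11 are in a list of 30 textbook liver genes, written after such genes were seen to be low on array 2, among them Afp (0.95 in the female and -4.14 in the male pair), Ahsg (0.93 and -3.20) and Alb (0.90 and -2.66), and its 27 measured members had medians of 0.50 on array 1 and -2.63 on array 2. A dye bias of the probes would make the turned ratios of the 2 arrays add up to 0, but their median sum was -2.08. Liver-type RNA in the control RNA of the male pair stays open as a candidate explanation, because the 88.9% of members at least 1.5-fold lower on array 2 come from a list that holds the genes that prompted it, although that RNA stood apart in its normalized log2 levels of Afp (13.1), Ahsg (14.3) and Alb (13.9), which were at most 11.6 in the other three. It would also leave aside that 22 of the 27 were higher on array 1, 11 of them at least 1.5-fold. A genotype effect that differs between the sexes stays open too, because the largest number of pairs of one sex is 1.

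Y-linked transcripts were present on the array whose labels are female in both channels. Ddx3y was higher in the Rbpj-cKO RNA by 4.23 and Eif2s3y by 4.26. An exchange of the female and male Rbpj-cKO RNAs would leave the male pair without Y-linked transcripts in the Rbpj-cKO channel, but the higher ratio there was -0.19. A dye bias would make the turned ratios add up to 0, but the smaller sum was 3.69. Male RNA mixed into the Rbpj-cKO RNA labelled female may account for the values, since Ddx3y stood at 25.6% and Eif2s3y at 20.9% of the level in the male RNAs, a ratio of 1.23, while Xist was near the control level (-0.36 and 0.14 for its 2 probes). The shares were worked out for these genes only. Uty was also higher on this array (1.08 and 0.95 for its 2 probes), and Kdm5d was not well above background there. Ddx3y and Eif2s3y were well above background in the control RNA too (log2 levels 7.08 and 7.70). No biological explanation was tested.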

How the results depend on the processing

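Removing the filter on dim probes left the size-rule counts at 85 and 168. With the offset at 16 the counts were 120 and 206, and with no background subtraction 112 and 194. With 1 array left neither limma, the correlation nor the list tests can be run. No paired analysis was possible because each ratio is already a within-array pair of a single group. The 4 channels in a 2-group fit and the eBayes settings do not alter ratios, so the counts by size and the correlation have no value there. Of the alternatives tried for each count, 12 of 14 left the number of genes called higher at 0. The exceptions were eBayes with trend and robust settings (46) and an adjusted p under 0.1 (28). For genes called lower these gave 49 and 36, and the count fell from 1 to 0 with the scanner's log ratio, median centring, scaling between arrays, the deposited series table and the 4 channels in a 2-group fit. The cause was not tested. With trend and robust settings Rbpj was called, with an adjusted p of 0.0310 and the same log2 ratio of -1.01, and over all alternatives its adjusted p ranged from 0.0310 to 0.579. Genes at least 1.5-fold higher on both arrays numbered 247 with the scanner's log ratio, 154 with the series table and 15 at 2-fold, and those lower 265 with the scanner's log ratio and 48 at 2-fold. Of the main 85 and 168, the scanner's log ratio kept 85 and 166. With each replicate left out, 202 to 258 genes were higher and 292 to 783 lower by size on the remaining array, which drops the condition on the other array. The correlation moved to 0.474 with the scanner's log ratio, 0.169 with median centring, 0.422 with no filter and 0.442 with the series table. The number of lists called went from 16 to 0 with an estimated correlation and to 0 with fry, and was 12 to 16 otherwise. The estimated correlation and fry could hardly call a list on 1 residual degree of freedom. Among single lists 14 values changed direction, none of a called list. These adjusted p were 0.970, 0.992, 0.963, 0.978, 0.849, 0.943, 0.849, 0.958 and 0.978 for leukocyte markers, with the scanner's log ratio, offset 16, scaling, the stricter filter, each probe alone, the series table, the GC regression, the 4-channel fit and fry. For injury genes they were 0.898 with the scanner's log ratio, 0.574 with no filter and 0.908 with the series table, and with fry they were 0.597 for Notch targets and 0.978 for nerve markers. Of the comparisons of named genes with the alternatives, 1175 were labelled the same, while 20 became called with trend and robust settings and 5 lost a call, all of Ucp1. The 1175 include leaving out each replicate, where no adjusted p exists and a change of direction could be marked only for Ucp1. They therefore do not show that a gene kept its direction on each array.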

Other observations

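The tests of explanations in this part were chosen after the values were seen, whereas limma and the steroidogenic cell list were fixed before. Of the steroidogenic cell list, which was not called as a group (camera adjusted p = 0.281), Akr1b7, an aldo-keto reductase found in renin cells and the adrenal cortex, had -0.61 on array 1 and -0.99 on array 2 (adjusted p = 0.0123 over the list alone). The following 4 genes, outside the rule for naming genes, were chosen after their values were seen and stand for no group. Ren1, which encodes renin, had -0.73 on array 1 and -1.32 on array 2 (adjusted p = 0.159 in limma), and Ren2, its near-identical copy, -0.93 and -1.61. Itga7, an integrin of muscle, had -0.81 and -0.80, and Olfr78, an olfactory receptor of vascular cells, -0.76 and -0.80. None of the 5 passed the threshold adjusted over all genes. Ren1 and Ren2 are so alike that their probes were not taken to separate the transcripts.

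The lower pericyte markers can be set against the vessels and the fat in the same RNAs. A smaller amount of vessel tissue of every cell type remains a candidate explanation, because endothelium markers were also lower, with a mean of -0.18 against -0.32 for pericyte markers, and an exact permutation test over the 8 and 17 genes gave p = 0.158 (two-sided). Genes are not independent replicates, and this p does not show that the lists moved alike. Of the 8 pericyte markers, 3 lay below the lowest endothelium marker, and 1 was higher on both arrays. With Notch3, Heyl and Hey2 added, picked because they were lower, the permutation p was 0.0253, which decides nothing for that reason. For a smaller share of adipose tissue, the ratio on array 2 of the pericyte markers lower on array 1 was predicted from their ratio on array 1 and the adipocyte medians. The median of observed minus predicted was -0.104 (SD between markers 0.097), just outside the 0.1 within which the share would account for the values and by less than the SD. This share cannot be told apart from a genotype effect, because the vessels that come with fat may differ between the 2 control RNAs. An effect of Rbpj loss in the pericytes themselves stays open and untested.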
